A study of Mus musculus with 6 samples.

How the data were processed

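Contacts of chromatin were profiled by Hi-C in 6 libraries of E14 mouse embryonic stem cells, 2 each from cells given control esiRNA against EGFP, esiRNA against Smarca4 (Brg1KD) and esiRNA against Ino80 (Ino80KD). Per the labels, the replicate number of a library is also its batch, so replicate 1 of each group shares a batch, and so does replicate 2. Nothing in the labels says whether the replicates came from separate cultures, so the spread between these samples may be technical. Tests between libraries measure only that spread. The p-values from rotations along the genome, described below, measure where shifts lie and hold no spread between libraries.

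The authors deposited 1 file of subcompartment segments per library, in which each segment has a label and a score, the rank of its subcompartment in 8 equal steps from B.2.2 up to A.1.1. The scores are relative to each library and no normalization for depth is recorded. Per the submitters' processing notes, the reads were processed on mm10 with BWA, SAMtools, Juicer 2.0, HOMER and bedtools, named without their roles. Which tool called subcompartments and loops, and with which thresholds, is not given in the sources used here. The libraries hold 5044 to 5234 segments that cover 2393.6 to 2396.8 Mb, with a median segment of 350 kb. All segments lie on autosomes. The deposited loop lists, 1 for each group, are recorded with replicate 2 and named as merged, so they were taken as pooled from both libraries, which the labels do not state. They give only the positions of the 2 anchors of each loop, 10 kb each, with no score, count or p-value per loop. The files give no read numbers, so depth is unknown, and no interval that needs it was computed for the ranks.

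Segments were cut into 50 kb bins, and the 47717 bins with a rank in all 6 libraries were used. No pair of libraries held identical labels. The share of bins in A and in each subcompartment was compared by exact two-sided permutation of 2 against 2 libraries, with Benjamini-Hochberg adjustment over subcompartments and contrasts. Ranks were tested per bin with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 6 libraries in one fit on the groups, Benjamini-Hochberg threshold 0.05). Its p-values are not calibrated here, because 18941 bins have no residual spread. As a count without a model, bins were counted in which both libraries of a group lay beyond both of the other, beside the same count for the other splits of the same 4 libraries. Whether shifts repeat was measured as the share of bins that moved in both batches and moved the same way, against 1000 rotations of the differences along each chromosome. Shifts are given in classes, where 1 class is a step of the 8-step rank, and are positive towards A.

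Whether the batch numbers pair the libraries follows from the labels, which name the batch. Deviations from the group means correlated between libraries of the same batch with r = 0.0984 (control and Brg1KD), 0.102 (control and Ino80KD) and 0.0885 (Brg1KD and Ino80KD). Fits with and without batch as a block were both set before the data were examined, the fit without it being the one reported.

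Genes were placed by the RefSeq table of GRCm38.p6, the assembly that mm10 names, in the bin of their midpoint, and 20375 protein-coding genes were placed. The table has no strand, so the start of transcription, which the design called for, could not be placed; midpoints were used in its place, and for loops either end of a protein-coding gene. 18 gene lists were set beforehand: pluripotency, primitive endoderm, mesendoderm, neuroectoderm, trophectoderm, 2-cell-like, Hox clusters, BAF subunits, INO80 subunits, chromosome architecture, Polycomb subunits, DNA replication and cell cycle, ribosomal proteins, olfactory receptors, vomeronasal receptors, histone gene clusters, protocadherin clusters and fibroblast markers. Of 11 genes of the 2-cell-like list 9 were matched, and of the other lists all members. A list's mean shift over its members' bins was set against 10000 rotations of the genome-wide shift, two-sided, adjusted over lists and over both comparisons with control, and over the lists alone for the direct comparison.

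Genes and regions were named by a rule set before the data were examined. For each list the members in bins called by limma were counted by direction and up to 4 members of the list with the largest shift, in any bin and in order of name where tied, could be named, with Smarca4 and Ino80 always. Of these, members that limma did not call and that moved by 1 class or less were left out, apart from Gsc, Cdx2 and Nr5a2. The 5 regions each way with the largest summed shift were named, each with up to 4 genes, a region being a run of adjacent shifted bins. Loops were to be named by score, and as the lists have none, only those of pluripotency genes follow the rule; Smarca4 and the other loops were chosen after their values were seen, as was Pou5f1 as an example.

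Loops were matched between lists by identical 10 kb anchors, in the neighbouring bin, or within 20 kb, with exact Clopper-Pearson intervals at 95%, which cover counting error only. Lists displaced by 100 kb gave the matches expected from position alone. The subcompartment of an anchor was taken from bins in which both replicates of its group gave the same label. For the comparison of both knockdowns, which share their controls, unchanged groups were simulated against the same controls.

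The statistics were tested on simulated data made from Brg1KD and control over 47717 bins, with 1000 bins changed by 1 class and 1000 by 2 classes, and with differences between replicates held to 1 class. Limma recovered 41.7% and 37.5% of them, limma with a common variance 18.0% and 96.0%, and the count of non-overlapping bins 70.3% and 98.1%. Of the calls, 40.9%, 8.95% and 33.1% were of unchanged bins, so single bins called by limma are uncertain. The simulated replicates had the same label in 76.5% of the bins, more than the real ones, so the real error is not bounded by these shares. In groups simulated without a change, the list test gave p under 0.05 in 23 of 360 tests (6.39%) and the test of direction in 2 of 20.

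Alternatives were batch as a block, each library left out in turn, larger bins, quantile-normalized ranks, limma with trend and robust, a minimum shift, 4 classes instead of 8, whole gene bodies, wider matching of loops and longer loops. Other tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.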

Results

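Chromosome folding was measured by Hi-C, which records pairs of DNA segments that lie close together in the nucleus, in E14 mouse embryonic stem cells. The cells had received esiRNA, a pool of short interfering RNAs, against EGFP as control, against Smarca4 (the gene of Brg1, the ATPase of the esBAF chromatin remodelling complex) or against Ino80 (the ATPase of the INO80 remodelling complex), and were collected 48 h later. The groups are called control, Brg1KD and Ino80KD, with 2 libraries each, 1 from each of 2 batches. Per library, the genome was divided into 8 subcompartments, from A.1.1 (the most A-like, the gene-rich and active part of the nucleus) down to B.2.2 (the most B-like, the inactive part). Of 48009 bins of 50 kb, 47717 (99.4%) had a label in all 6 libraries and span 2385.85 Mb of the autosomes 1 to 19. For each group 1 list of chromatin loops was also given. These lists are recorded with replicate 2, but were treated as lists of pooled libraries because their names call them merged. The series title puts the question whether esBAF and INO80 act on subcompartments and on contacts of enhancers with promoters. The files hold no read depth, so the depth behind each library is unknown.

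The knocked-down genes themselves stayed in the most A-like subcompartment. Smarca4 (chromosome 9, 21616106 to 21704230, mm10) and Ino80 (chromosome 2, 119373042 to 119478685) lay in A.1.1 in all 6 libraries, as did Pou5f1 (chromosome 17, 35506032 to 35510777), a core factor of pluripotency. Hi-C gives no transcript level, so the strength of either knockdown was not measured here. The replicates carried the same label in 68.9% of the bins in control, 68.3% in Brg1KD and 69.5% in Ino80KD. Between Brg1KD and control libraries the label was the same in 62.1% to 66.0% of the bins, and between Ino80KD and control libraries in 65.8% to 71.7%. Every pair of libraries was within 1 class of each other in at least 95.6% of the bins.

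Less of the genome lay in A after either knockdown. The A subcompartments held 39.6% ± 0.0919 of the bins in control (SD, n = 2), 38.6% ± 0.259 in Brg1KD and 38.5% ± 0.105 in Ino80KD. Brg1KD was 0.944 percentage points below control (a difference of -0.944, and -1.06 and -0.826 within the batches). For Ino80KD the difference was -1.05 points (-1.06 and -1.04 within the batches). At the B end, B.2.2 held 22.1% ± 1.08 of the bins in control, 23.9% ± 1.38 in Brg1KD and 23.6% ± 2.02 in Ino80KD. Single libraries moved the B.2.2 difference from control. In Brg1KD it was 1.80 points, but 1.04 without control replicate 1, 2.78 without Brg1KD replicate 1 and 0.827 without Brg1KD replicate 2. In Ino80KD it was 1.52 points, but 0.755 without control replicate 1, 2.28 without control replicate 2, 2.95 without Ino80KD replicate 1 and 0.0933 without Ino80KD replicate 2. A.1.2 held 10.3% ± 0.304 in control against 9.54% ± 0.790 in Brg1KD and 9.47% ± 0.0252 in Ino80KD, while A.2.2 held 6.90% ± 0.0489 against 7.29% ± 0.0919 and 7.22% ± 0.228. In A.1.2 the Brg1KD difference of -0.790 points was -1.35 without Brg1KD replicate 1 and -0.232 without Brg1KD replicate 2, and in A.2.2 the Ino80KD difference of 0.317 points was 0.156 without Ino80KD replicate 1 and 0.479 without Ino80KD replicate 2. Neither knockdown overlapped the controls in the shares of A, A.1.2 and A.2.2, and in B.2.2 this held for Brg1KD but not for Ino80KD. The exact two-sided permutation test gave p = 0.333 for the A share of either knockdown, the smallest that 2 libraries against 2 allow, so no difference of shares could reach a threshold of 0.05, and the adjusted p over subcompartments was 0.762 or higher.

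More bins were shifted towards B than towards A in Brg1KD, in regions with a median length of 200 kb towards B and 150 kb towards A. The region with the largest summed shift towards B (chromosome 12, 40200001 to 40850000) holds Ifrd1, Zfp277 and Dock4, an activator of small GTPases, and moved from A.1.2 to A.2.1 and A.2.2, a mean of -1.46 classes. The region of Glrp1 and Arl4c, a small GTPase (chromosome 1, 88500001 to 88800000), moved by -2 classes from A.2.1 to B.1.1, and so did a stretch with no gene placed in it on chromosome 5 (74650001 to 74950000). The region of the tyrosine kinase gene Fer, with Pja2 and Man2a1 (chromosome 17, 64000001 to 64700000), went from B.1.1 to B.1.2, and that of Atrnl1 (chromosome 19, 57500001 to 58150000) shifted by -1 class. Towards A, a stretch of 1300 kb on chromosome 7 (19500001 to 20800000) with 48 protein-coding genes, the first by position Bloc1s3, Trappc6a, Nkpd1 and Ppp1r37, rose from A.1.2 to A.1.1. Of these 48 genes, 19 are vomeronasal receptors.

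The other 4 leading regions towards A in Brg1KD lay on chromosomes 1, 2, 3 and 7. The pentraxin genes Crp and Apcs, with Olfr16 and Olfr1408 (chromosome 1, 172650001 to 173250000), and Cst10 (chromosome 2, 149250001 to 149750000) each moved from B.2.2 to B.2.1. On chromosome 7 (5100001 to 5600000), Rfpl4, Rasl2-9, Vmn1r55 and Vmn1r56 moved from B.1.2 to B.1.1, in a region where 7 of 10 genes are vomeronasal receptors. A stretch of chromosome 3 without a gene placed in it (66550001 to 66950000) shifted by 1.25 classes.

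By limma with Benjamini-Hochberg adjustment, 2304 bins (4.83%, 115.2 Mb) were shifted in Brg1KD, 1576 towards B in 369 regions and 728 towards A in 200 regions, and 2903 passed without adjustment. The bins towards B carried 5.14 protein-coding genes per Mb and those towards A 8.35, against 8.54 in all bins. In 693 bins all libraries of the groups lay on opposite sides of the A/B border, 478 of them (23.9 Mb) going from A to B and 215 (10.75 Mb) from B to A. The ranks have only 8 steps, so 18941 bins had no residual spread, and 2294 of the 2304 calls were among these bins, in which the libraries of each group gave the same label. Only 91 of the 2304 were also among the 1622 bins (488 towards A, 1134 towards B) called with a common variance for all bins, which was chosen after seeing the data.

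In 4923 bins (10.3%) both Brg1KD libraries lay on the same side of both controls, 3431 (69.7%) towards B and 1492 towards A. The other splits of the same 4 libraries gave 2904 bins (6.09%) between the batches and 1851 (3.88%) for the crossed split. They measure the spread between libraries only roughly. Each of their sides mixes knockdown and control, so an effect of the knockdown would lower these counts, and the split by batch also holds any difference between the batches. By limma those splits had 1329 and 817 bins, and 343 and 174 bins lay on opposite sides of the A/B border. The direction of the shift was the same in both batches for 72.0% of the 8000 bins that moved in both, against a mean of 52.9% (49.0% to 57.4%) in 1000 rotations along the chromosomes (two-sided rotation, that is permutation, p = 0.001, the smallest these rotations can give).

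**Figure D1:**
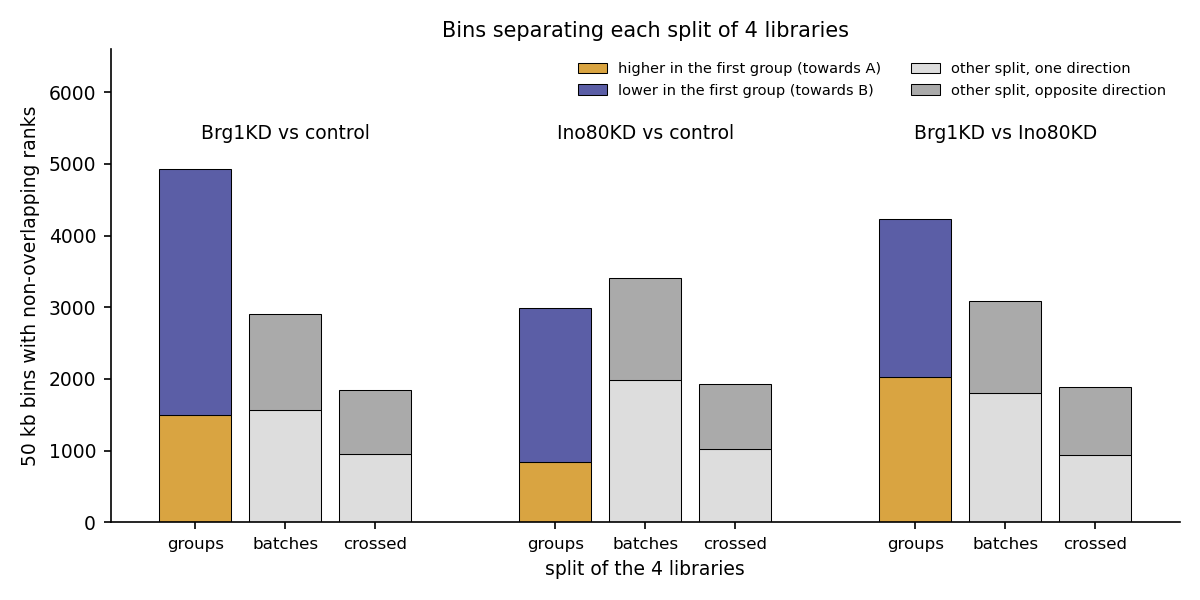
Number of bins in which both libraries of one side lie beyond both of the other, for the real groups and for the other splits of the same 4 libraries, by direction. For Brg1KD the real groups give 4923 bins against 2904 and 1851, and for Ino80KD 2984 against 3407 and 1936.

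Of the 20375 protein-coding genes placed, 304 were in bins shifted towards A in Brg1KD and 405 in bins shifted towards B. Of 24 pluripotency genes placed, 2 were in shifted bins, both towards A, namely Lefty1 (chromosome 1, 180935022 to 180938401) and its neighbour Lefty2 (180893108 to 180899107), inhibitors of Nodal signalling, which rose from A.1.2 to A.1.1. The mean over the list was 0.0625 classes. With a common variance, none of the list members named here as called in Brg1KD passed (adjusted p = 0.236 by limma). Each of them moved by 1 class, and in Brg1KD that fit passes only shifts of at least 1.5 classes, so none could pass. Of 11 trophectoderm genes, Ascl2 (chromosome 7, 142966822 to 142969264) fell from A.1.2 to A.2.1 and Elf5 (chromosome 2, 103412098 to 103450989) from A.2.1 to A.2.2, both transcription factors of the trophoblast lineage, while the list mean was 0.100. Cdx2 of the same list went the other way, from A.1.2 to A.1.1 in both Brg1KD libraries, but was not called, as described below. Smarce1 (chromosome 11, 99209047 to 99231017), a subunit of the BAF complex itself, fell from A.1.2 to A.2.1, and was the 1 of 12 BAF subunits in a shifted bin (list mean -0.125). None of the 14 INO80 subunits was (0.0357).

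A part of the histone genes on chromosome 13, in 4 neighbouring bins, was called in both directions. Of 67 histone genes, 13 were in bins shifted towards B, all 13 from A.1.2 to A.2.1, among them H1f1 (23763668 to 23764412), H1f2 and H1f6. H1f4 (23621777 to 23622558) rose from A.1.2 to A.1.1, as did H2bc6 in the same cluster and H1f8 on chromosome 6 (115944931 to 115950242), both named after their values were seen. The list mean was -0.0588 classes (permutation by rotation, p = 0.947). Rps27a (chromosome 11, 29545842 to 29548040), which encodes a ribosomal protein fused to ubiquitin, fell from A.1.2 to A.2.1 as the 1 of 87 ribosomal protein genes in a shifted bin (list mean 0.0238). Histone and receptor families hold near-identical copies, so their values are uncertain where reads could map to several of them.

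The vomeronasal receptor genes, pheromone receptors of sensory neurons, were the 1 of 18 lists that passed in Brg1KD. Their mean shift was 0.172 classes towards A, against a mean of -0.0844 in rotations (permutation by rotation, p = 0.0009, adjusted p = 0.0324 over lists and both knockdowns), with 29 of 334 members in bins shifted towards A and 2 towards B. These 29 genes lie in 20 bins, most of them in regions named above, with 19 in the 1300 kb of chromosome 7 and 7 in the region from 5100001. Without the members in these regions the mean was 0.116 (unadjusted permutation p = 0.0075, a test chosen after seeing the data), with 3 towards A. The members on chromosome 7 carried the list mean: the 161 there had a mean of 0.376, and the 173 on other chromosomes -0.0296 (permutation p = 0.568), a split chosen after seeing the data. The members with the largest shifts, none called by limma (adjusted p of 0.413 or higher), went both ways: Vmn2r96 (chromosome 17, 18573255 to 18598157) by -2 and Vmn2r100 (19504811 to 19532060) by -1.5 classes, and Vmn2r129 (chromosome 4) and Vmn2r37 (chromosome 7) by 1.5 (adjusted p = 0.00207 for Vmn2r96 and 0.0466 for the others by limma with a common variance). Within batch 1 the list mean was 0.0634 (adjusted permutation p = 0.840) and within batch 2 0.280 (0.0108). It was 0.0821 without Brg1KD replicate 1 (adjusted permutation p = 0.263) and -0.0261 without control replicate 2 (0.678). Olfactory receptors had a mean of 0.0289 (6 of 1101 towards A, 1 towards B) and protocadherin clusters of 0.636 (0 in batch 1 and 1.27 in batch 2). Their unadjusted permutation p of 0.038 and 0.0459 gave an adjusted p of 0.344.

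The remaining lists had no member in a shifted bin in Brg1KD. Their mean shifts were -0.292 for fibroblast markers, included as a sign of other cells in the culture, -0.269 for neuroectoderm and for the Hox clusters, -0.250 for primitive endoderm and 0.0556 for 2-cell-like genes. The mesendoderm, Polycomb, chromosome architecture, and DNA replication and cell cycle lists had a mean of 0 classes. Members with large shifts that limma did not call were Lama1 (chromosome 17, 67697127 to 67822645), a laminin chain of primitive endoderm, with -1.5 classes, and the proneural gene Neurog1 (chromosome 13, 56250478 to 56252180), also with -1.5. Their adjusted p was 0.413 by limma and 0.0466 by limma with a common variance. The fibroblast marker S100a4 (chromosome 3, 90603770 to 90606045) also had -1.5 classes, but its groups overlapped, with A.1.1 and A.1.2 in the controls and A.1.2 and A.2.2 in Brg1KD (adjusted p = 0.906 and 0.0466 by the same limma fits). The largest member shift was that of the olfactory receptor gene Olfr1417 (chromosome 19, 11828077 to 11829024), with -4 classes (adjusted p = 0.137 by limma, 7.95e-14 by limma with a common variance), in the first bins of an A segment of the controls, which began 2 bins later in both Brg1KD libraries. Olfr11 and Olfr1360 on chromosome 13 had 2 classes (adjusted p = 0.808 by limma, 0.00207 with a common variance), as did Olfr1274 on chromosome 2, in which the groups overlapped. The bin of Neurog1 lay at a segment border in both Brg1KD libraries and in control replicate 2. Gsc had -1 and Cdx2 had 1 class (adjusted p = 0.733 by limma).

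Ino80 knockdown also shifted more bins towards B than towards A. The leading region towards B (chromosome 5, 128450001 to 129300000) holds Fzd10, a Wnt receptor, Piwil1, of the piRNA pathway, Rimbp2 and Stx2, and moved by -1 class. Also on chromosome 5, the region of Fip1l1, Lnx1, Chic2 and the homeobox gene Gsx2 (74500001 to 75150000) moved by -1 class. The others were a gene-free stretch of chromosome 10 (83800001 to 84350000, -1.18 classes), the region of Ifrd1, Zfp277 and Dock4 that also led in Brg1KD (from A.1.2 to A.2.1), and that of the potassium channel subunit gene Kcnab1 (chromosome 3, 64750001 to 65350000, from B.2.1 to B.2.2).

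Towards A, the first 2 regions of Ino80KD were those of Brg1KD, the 1300 kb on chromosome 7 and the Crp and Apcs region of chromosome 1, with the same labels. The region of Rad18, a ubiquitin ligase of DNA repair, and Srgap3 (chromosome 6, 112600001 to 113000000) rose from A.2.1 to A.1.2. Stretches without a gene placed in them on chromosome 12 (25500001 to 26000000) and chromosome 13 (100850001 to 101250000) rose from B.2.2 to B.2.1 and from B.2.1 to B.1.2. Chromosome 5 held 216 of the bins shifted towards B and 14 of those towards A, and chromosome 19 held 78 and 0.

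By limma with Benjamini-Hochberg adjustment, 1538 bins (3.22%, 76.9 Mb) were shifted in Ino80KD, 1130 towards B in 262 regions and 408 towards A in 137, and 1797 passed without adjustment. The bins towards B carried 5.59 protein-coding genes per Mb and those towards A 9.17, with no matched background here either. From A to B went 294 bins (14.7 Mb) and from B to A 77 (3.85 Mb). The split of the same 4 libraries by batch, which also holds any difference between the batches, gave 1710 limma bins and 391 A/B changes, more than the real groups, and the crossed split, in which each side holds 1 library of each batch, gave 854 and 219, fewer than the real groups. In 2984 bins (6.25%) both Ino80KD libraries lay beyond both controls, 2146 of them (71.9%) towards B, against 3407 (7.14%) for the split by batch and 1936 (4.06%) for the crossed split. With batch as a block, limma called 1679 bins, and with a common variance 326 (340 and 240 in the other splits) or, with that block, 932. A common variance calls all bins above one size of shift, 2 classes without the block and 1.5 with it, and at 1.5 classes the other splits gave 944 and 751 bins.

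The direction repeated in both batches for 58.8% of the 5870 bins that moved in both, against a mean of 53.4% (48.9% to 58.6%) in rotations (two-sided permutation p = 0.001, the smallest possible). When each Ino80KD library was set against the control of the other batch instead, the share was 46.9%, below an even split, against 62.4% for Brg1KD. Only 27 of the 1538 limma bins were also called with a common variance.

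**Figure D2:**
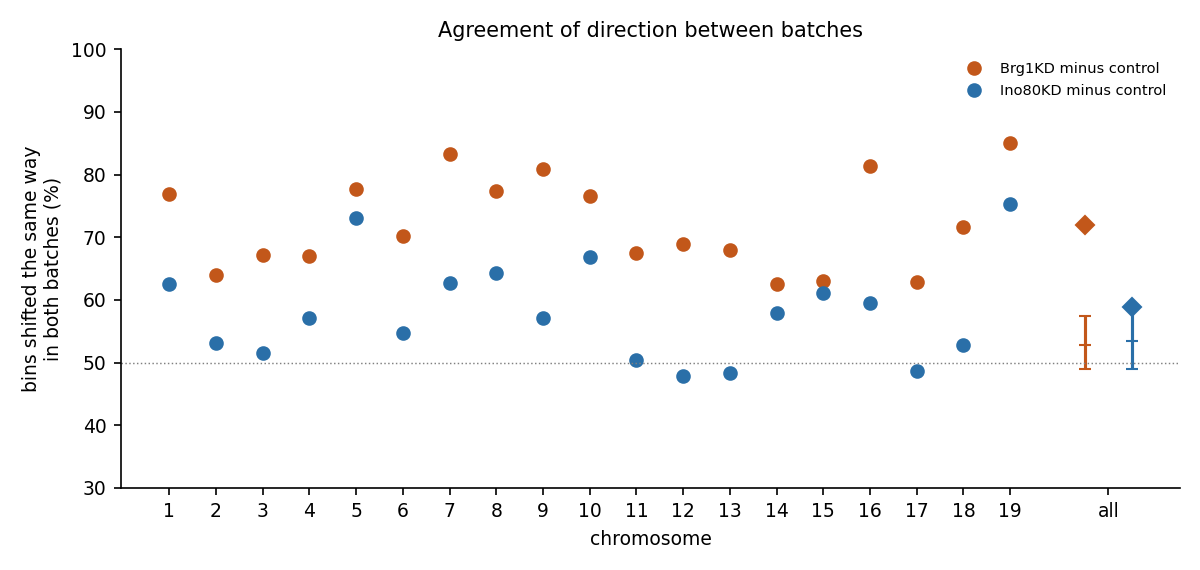
Share of bins that moved the same way in both batches, in percent of the bins that moved in both, with the range of 1000 rotations, and the same share on each autosome. Brg1KD reaches 72.0% and Ino80KD 58.8%, and Brg1KD is higher on 19 of 19 chromosomes.

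Lefty1 and Lefty2 rose from A.1.2 to A.1.1 in Ino80KD too, the 2 of 24 pluripotency genes in shifted bins (list mean 0.104 classes). With a common variance, none of the list members named here as called in Ino80KD passed (adjusted p = 0.362 by limma). Each of them moved by 1 class, and in Ino80KD that fit passes only shifts of at least 2 classes, so none could pass. Cer1 (chromosome 4, 82881751 to 82885151), a secreted antagonist of Nodal and BMP, crossed from B.1.1 to A.2.2, the 1 of 12 mesendoderm genes in a shifted bin (0.0833). Rpl7 (chromosome 1, 16101295 to 16104433), of the large ribosomal subunit, fell from A.2.2 to B.1.1, the 1 of 87 ribosomal protein genes (0.0179). All 15 histone genes in shifted bins, of 67, fell from A.1.2 to A.2.1 in the chromosome 13 cluster, H1f1, H1f2, H1f4 and H1f6 included (list mean -0.235). Olfactory receptors had 18 of 1101 members in bins towards A and 9 towards B (-0.00263). Olfr1339 to Olfr1342 on chromosome 4 (118689152 to 118735478) had the largest shift, 2.5 classes (adjusted p = 0.458 by limma, 4.27e-05 by limma with a common variance). Vomeronasal receptors had 19 of 334 members towards A and 2 towards B (0.0187), and all 19 lie in 11 bins of the 1300 kb region of chromosome 7. Without them the list mean was -0.0233. Over all 334 members the mean was -0.149 and 0.187 without Ino80KD replicates 1 and 2. It was 0.216 and -0.179 without control replicates 1 and 2. Vmn2r100 had -1.5 classes and Vmn2r129, Vmn2r13 and Vmn2r56 had 1.5, none called (adjusted p of 0.662 or higher by limma, 0.0811 with a common variance), and in Vmn2r129 and Vmn2r56 the groups overlapped.

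No list passed in Ino80KD: the smallest adjusted p was 0.344, and 1 list, the fibroblast markers, had an unadjusted p under 0.05 (-0.375 classes, permutation p = 0.0481). The other lists, without a member in a shifted bin, had means of -0.222 (2-cell-like), -0.0455 (protocadherin clusters), 0 (INO80 subunits, Polycomb and Hox clusters), 0.0357 (DNA replication and cell cycle), 0.0417 (BAF subunits), 0.0625 (chromosome architecture), 0.100 (trophectoderm), 0.154 (neuroectoderm) and 0.179 (primitive endoderm). Pdgfra (chromosome 5, 75151322 to 75198206), a receptor of primitive endoderm, was in B.1.2 and B.1.1 in the controls and in A.2.1 in both Ino80KD libraries, 2.5 classes higher (adjusted p = 0.162 by limma, 4.27e-05 by limma with a common variance). This is a single bin at a border: the A segment before it ended 1 bin later in Ino80KD, while that segment fell from A.1.2 to A.2.1 and the next bins were in B.1.2. The neural gene Sox1 (chromosome 8, 12395519 to 12399555) was in A.2.1 in both controls and A.1.1 in both Ino80KD libraries (adjusted p = 0.318 and 0.0037 by the same limma fits), also in a single bin beside a segment of higher rank, and Nr5a2 was 1 class higher (0.970). Nr5a2 was in A.1.2 in both controls and A.1.1 in both Ino80KD libraries. At Sox1 and Nr5a2 the spread in the shared fit therefore came from the Brg1KD libraries.

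The knockdowns were then set against each other. The regions that led towards A in Brg1KD relative to Ino80KD were the Fzd10 region of chromosome 5 (128400001 to 129300000), the Kcnab1 region of chromosome 3, the chromosome 10 stretch from 83800001, and the Cst10 and chromosome 3 stretches that had moved in Brg1KD. Those towards B included Pik3r4 with the collagen genes Col6a6, Col6a5 and Col6a4 (chromosome 9, 105600001 to 106150000), in A.2.1 in Ino80KD and control and A.2.2 in Brg1KD. The region of Boc, a coreceptor of hedgehog signalling, with Nepro, Gtpbp8 and Cd200r1 (chromosome 16, 44450001 to 45000000), and that of the sperm channel gene Catsperb with Tc2n (chromosome 12, 101100001 to 101700000), were also 1 class lower in Brg1KD. Gene-free stretches of chromosome 18 (8300001 to 8850000) and chromosome 2 (106400001 to 106650000, -2 classes) completed the list.

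By limma, 1890 bins (3.96%, 94.5 Mb) differed between the knockdowns, 867 higher in Brg1KD and 1023 higher in Ino80KD, against 1469 and 862 in the other splits. Both Brg1KD libraries lay beyond both Ino80KD libraries in 4228 bins (8.86%), against 3085 (6.47%) and 1885 (3.95%). With a common variance 515 bins were called (344 and 288 in the other splits), 72 of them among the 1890, and 1475 with batch as a block. The 1475 are the bins with a shift of at least 1.5 classes, of which the other splits gave 945 and 763. No list passed the rotation (permutation) test (smallest adjusted p = 0.0909), with 4 at an unadjusted p under 0.05. These were primitive endoderm (-0.429 classes, permutation p = 0.0074), neuroectoderm (-0.423, p = 0.0101), vomeronasal receptors (0.153, p = 0.0197) and protocadherin clusters (0.682, p = 0.0431). Single libraries moved these means. Neuroectoderm had -0.154 and -0.692 without Brg1KD replicates 1 and 2, and vomeronasal receptors had 0.321 and -0.0149 without Ino80KD replicates 1 and 2. Without each library in turn, primitive endoderm ranged from -0.536 to -0.321 and protocadherin clusters from 0.273 to 1.09. The share of bins with the same direction in both batches was 13.1 percentage points higher in Brg1KD than in Ino80KD (95% interval 10.0 to 16.4 over resampled chromosomes, which covers the spread between chromosomes and not that between libraries).

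A part of the shifted bins was called in both knockdowns. Of the limma bins, 775 were shifted towards B in both and 214 towards A; most calls lie in the bins without residual spread, so no number expected without a change is given for them. Of the Brg1KD bins called towards A, 7 were called towards B in Ino80KD, and of those towards B 2 were called towards A. Both comparisons use the same controls, so part of this sharing may come from them. Over non-overlapping bins 1005 towards B were shared, where independent lists of these lengths would share 154, and 274 towards A, where they would share 26.2. Simulated unchanged groups against the same controls had shorter lists (means of 548 and 506 bins towards B, 817 and 801 towards A) and shared a mean of 12.9 towards B, where independent lists would share 5.81, and 26.7 towards A, against 13.7. Across bins, which are not independent replicates, the shifts of the knockdowns had r = 0.458 (covariance times 1000 of 1.92), and simulated unchanged groups had r = 0.50 (1.77), an excess of 0.144 in covariance. The simulated spread came from differences between replicates, which hold any batch difference, so the excess may be too small. Differences taken in opposite batches, which share no library, had r = 0.0497 and 0.0481 (permutation p = 0.001, the smallest the rotations can give). Their covariances times 1000 were 0.361 and 0.358, above that excess.

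**Figure D3:**
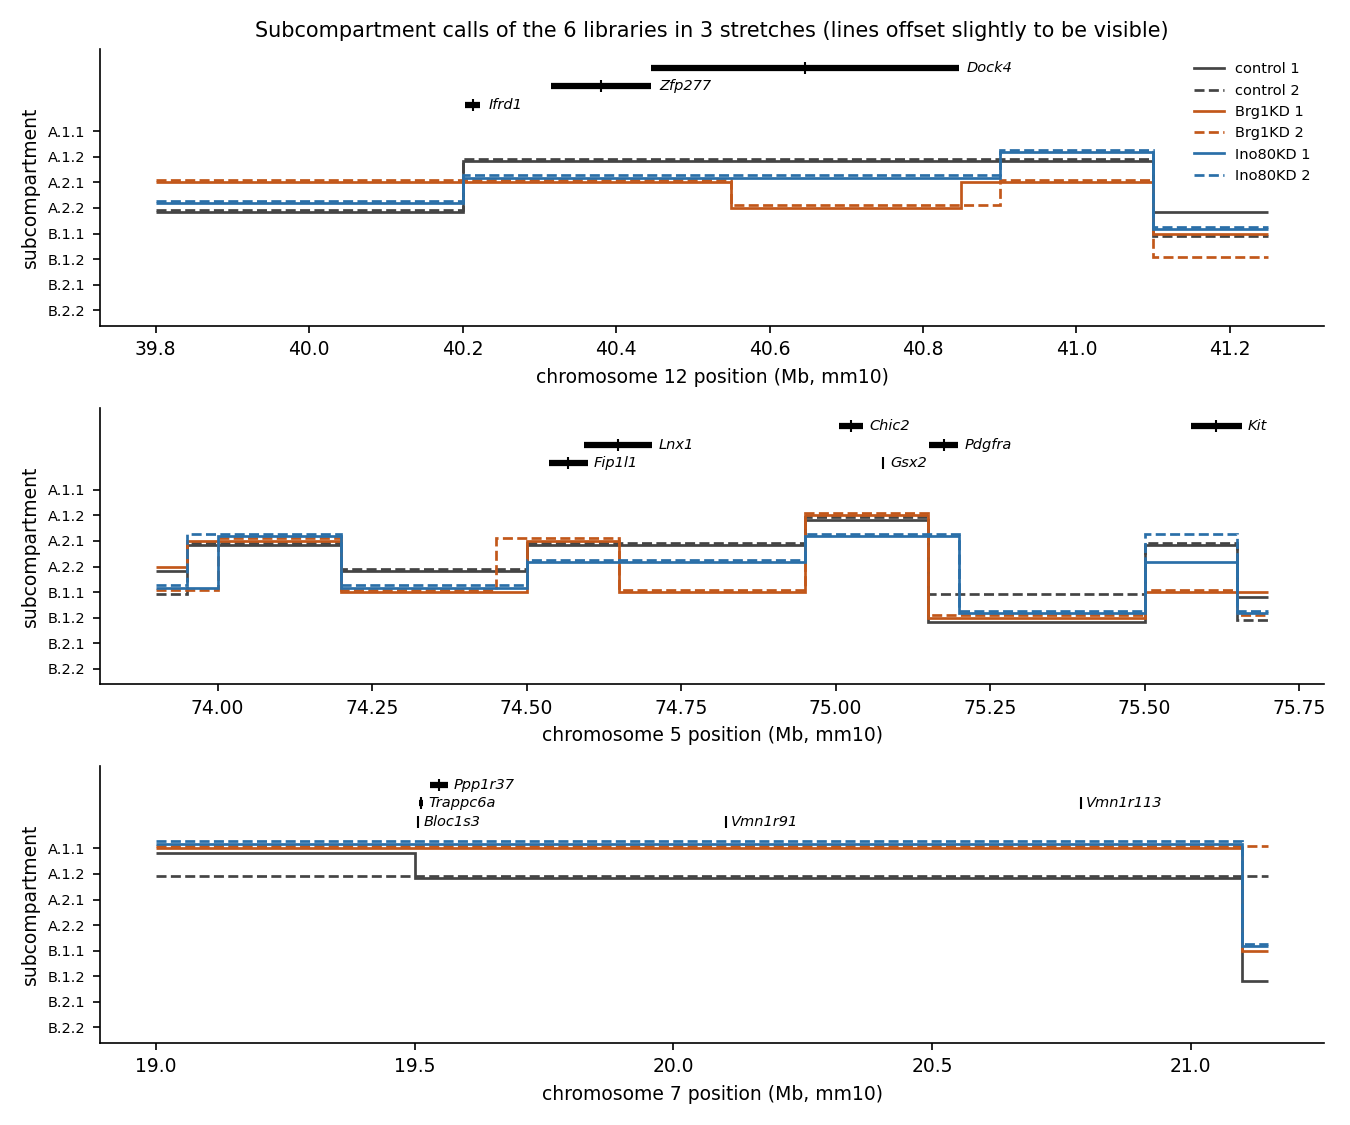
Subcompartment, from B.2.2 to A.1.1, along 3 stretches of chromosomes 12, 5 and 7 against the position in Mb (mm10), with a line for each of the 6 libraries, slightly offset so that equal labels can be seen, and genes as bars with a tick at the midpoint. Over Ifrd1, Zfp277 and Dock4 all knockdown libraries lie below both controls, and on chromosome 7 all lie in A.1.1 where the controls are in A.1.2.

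Loops were similar in length in all 3 lists, and the Ino80KD list held the fewest. The control list held 5903, the Brg1KD list 6013 and the Ino80KD list 5475, each with a median length of 250 kb and an interquartile range of 150 kb to 450, 440 and 430 kb. Of the loops, 145, 165 and 145 were on the X chromosome. On every autosome the Ino80KD list held fewer loops than the control list (0.877 to 0.992 times), while the Brg1KD list went both ways (0.909 to 1.09 times). Depth is unknown, so its part in this could not be measured. An identical pair of 10 kb anchors was found for 45.7% (95% interval 44.4% to 47.0%, exact binomial) of the control loops in the Brg1KD list and for 46.4% in the Ino80KD list. Allowing the neighbouring bin gave 77.0% and 75.1%, where lists displaced by 100 kb gave at most 0.280%. In no other list within 20 kb were 660 control loops (11.2%), 907 Brg1KD loops (15.1%, 14.2% to 16.0%) and 502 Ino80KD loops (9.17%, 8.42% to 9.96%). These shares also depend on how many loops each list holds. There are no replicates, so none of these differences could be tested, and the intervals cover counting error only.

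Loops at genes of cell identity were listed in several groups. Sox2 (chromosome 3, 34649995 to 34652461), a core pluripotency factor, had 1 loop in control, 0 in Brg1KD and 1 in Ino80KD, but a Brg1KD loop had both anchors within 20 kb of those of the control loop. Mycn had 1 in each list, and Tbx3 (chromosome 5, 119670534 to 119684724) had 0, 1 and 1. The Tbx3 loops were different ones. That of Brg1KD (100 kb) had no partner within 20 kb in either other list, and that of Ino80KD (1500 kb) had a partner in both. Of the 25 pluripotency genes 2, 2 and 3 had a loop at an end of the gene (8%, 8% and 12%), against 11.1%, 11.1% and 10.7% of all protein-coding genes. Smarca4, the target of one knockdown, had 0 loops in control and 2 in each knockdown, from the anchor at 21610001 on chromosome 9 to those at 21860001 and 21940001. Among genes named after their values were seen, Cdx2 had 2 in control, 3 in Brg1KD and 0 in Ino80KD, though both control loops had an Ino80KD partner within 20 kb, and Pax6 had 1, 0 and 0.

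An end of a protein-coding gene lay in at least 1 anchor of 36.3% of the control loops, 35.4% of the Brg1KD loops (34.2% to 36.6%) and 36.6% of the Ino80KD loops, against 28.8% to 29.5% for anchors displaced by 100 kb. In both anchors it lay for 6.62%, 6.39% and 7.56%. Among anchors in bins where the replicates agreed, 68.6% lay in A in control, 66.8% in Brg1KD and 68.5% in Ino80KD. Of all bins on which the replicates of the group agreed, 41.3%, 40.4% and 40.6% were in A. B.2.2 was the most depleted, at 0.278, 0.285 and 0.250 times its share of those bins. A promoter could not be told from the far end of a gene, since the gene table gives no strand.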

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

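The tests of noisier libraries, of an offset of the class borders, of the shared controls and of loop positions that move by a bin were chosen after the results they bear on were seen.

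Brg1KD and Ino80KD differed from each other: by limma in 1890 bins, against 1469 for the split of the same libraries by batch, with too few splits for a share under 0.05. The share of bins that moved the same way in both batches was 13.1 percentage points higher in Brg1KD than in Ino80KD, with an interval over chromosomes alone, so this difference was not tested against the spread between libraries. Without each chromosome's mean 99.0% of the correlation between the Brg1KD batches was kept, but these means held only 0.674% and 1.19% of the variance and a moved border shifts the bins beside it alone, so moves of class borders stay open. Noisier Ino80KD libraries would share fewer labels between replicates, but they shared 1.22 points more than those of Brg1KD (95% interval over chromosomes -0.173 to 2.72), which includes 0 and leaves this open. A difference between the effects of the remodellers, a weaker Ino80 knockdown and a difference in depth may each contribute, and none of them was tested.

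Both knockdowns had a net shift towards B. One offset of the class borders that moved bins towards B would leave no more bins shifted towards A than the other splits of the libraries give in one direction. In Brg1KD 488 bins had a mean shift of at least 1.5 classes towards A, against at most 532 in the split by batch and 393 in the crossed split. In Ino80KD 342 had, against 505 and 397, but at 2 classes 134, against 196 and 120, so whether an offset may underlie the net shift stays open in both. The A shares of the knockdowns differed by -0.105 points (Ino80KD minus Brg1KD), less than either from control, so a deviation of the shared controls cannot be told apart from an effect common to both knockdowns, as there is no other control group.

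An identical partner in another list was found for 41.3% to 50.0% of the loops. When the neighbouring 10 kb bin was allowed, the lowest share was 70.9%, against at most 0.280% for control loops and displaced lists, which is consistent with calls whose position moves by a bin. Among control loops, the highest share with an identical Ino80KD partner on any chromosome was 2.10 times the lowest, which was on the X chromosome, while for Brg1KD partners it stayed within 1.5 times, so differences between whole chromosomes stay open. A biological difference between the lists was not tested, since there are no replicates of them.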

How the results depend on the processing

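Alternatives chosen after seeing the data were the common variance, fixed sizes of shift, controls of the other batch, the neighbouring bin for loops, class-adjusted shifts, loops against shifts within each batch, A/B changes without each library, and the vomeronasal list without chromosome 7 or without the named regions (0.116 classes in Brg1KD and -0.0233 in Ino80KD). Named regions kept their direction, and limma called at least 50% of their bins, in all 140 values, and named genes were the same in 1020, with 12 stronger: Lama1 without either Brg1KD library, Neurog1, Pdgfra and (in both knockdowns) Vmn2r100 without either control, Nanog without Brg1KD replicate 1 and Vmn2r56 without Ino80KD replicate 2. In the named regions the replicates of each group had the same mean rank. Leaving out a library or adding the block therefore could not change their shift, and the 140 values are no independent check. Of the values of gene lists 229 were the same. Of lists not past the threshold, 30 values changed sign, 20 became 0 and 41 left a mean of 0. Of the values of single subcompartments 94 kept their direction and stayed within the spread between replicates, and 18 changed direction or moved further. Not run were the stricter loop threshold, as the lists have no score, and the reciprocal overlap of anchors and autosomes only, which change nothing for aligned anchors and autosomal bins. Depth is unknown, so what it limits could not be measured.

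With 250 kb bins limma called 363 (Brg1KD), 223 (Ino80KD) and 283 bins (direct comparison), and 1701, 1098 and 1523 did not overlap, of 9598 bins, fewer by construction. With 4 classes, which have fewer borders to cross, limma called 1311, 768 and 1068. With a common variance it called 326 bins in Ino80KD and 515 in the direct comparison, and with a block for batch as well 932 in Ino80KD, as the size of shift that passes fell from 2 to 1.5 classes.

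Subcompartments whose share did not overlap the controls numbered 3 in Brg1KD and 2 in Ino80KD. They were 6 and 7 under the replicate block (the same direction in both batches), a weaker condition, and 1 and 0 with 4 classes, of which there are fewer. They ranged from 3 to 8 and from 2 to 8 without one library (Brg1KD: 6 without Brg1KD replicate 1, 5 without control replicate 1 and 8 without control replicate 2; Ino80KD: 7 without Ino80KD replicate 1 and 8 without control replicate 2). Under the block within batch 1, 0 lists passed in Brg1KD.

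Without each library in turn, limma called 3851 to 5499 bins in Brg1KD, 2468 to 4707 in Ino80KD and 3289 to 4976 in the direct comparison, and 9449 to 10602, 7171 to 8705 and 8746 to 9698 bins did not overlap. Changes between A and B were 1291 to 1363 and 771 to 1029. Fewer libraries are easier to separate and leave more bins without residual spread (23932 to 24575), and the lone library is assumed to vary like the other groups. Lists past the threshold were 0 to 2 in Brg1KD (0 without Brg1KD replicate 1 or control replicate 2, 2 with olfactory receptors without Brg1KD replicate 2), 0 to 1 in Ino80KD (vomeronasal receptors without Ino80KD replicate 2 or control replicate 1) and 0 to 3 in the direct comparison (2 without Brg1KD replicate 2, 3 without Ino80KD replicate 1). The vomeronasal mean in Brg1KD ranged from -0.0261 (without control replicate 2) to 0.369 classes, and was -0.0296 without chromosome 7. The cause was not tested.

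With controls of the other batch, Ino80KD bins moved the same way in 46.9%. Batch differences then enter with opposite sign, but whether they lowered the share was not tested. In opposite batches, which share no library, the knockdown shifts had r = 0.0497 and 0.0481.

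Loops of at least 100 kb had medians of 280, 270 and 280 kb (control, Brg1KD, Ino80KD). Partners within 1 bin and within 20 kb were found for 77.0% and 80.5% of control loops in Brg1KD, 75.1% and 78.3% in Ino80KD, 75.6% and 79.1% of Brg1KD loops in control, 70.9% and 74.6% in Ino80KD, and 81.0% and 84.4% of Ino80KD loops in control, 77.8% and 81.9% in Brg1KD. A gene end within 5 kb of an anchor was found for 56.1%, 55.0% and 56.2%. Wider matching raises these shares by construction. By the labels of replicates 1 and 2 alone, 64.4% and 65.3% of control anchors, 62.6% and 64.0% of Brg1KD anchors, and 64.1% and 64.8% of Ino80KD anchors were in A. The shares given first were higher because they use only anchors in bins where the replicates agreed, 7808 of 11504 in control.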

Other observations

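The tests of loops against shifts were set before their results were seen; the split of shifts by subcompartment and the tests within each batch were chosen afterwards, and the genes named here after their values were seen.

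The mean shift differed between subcompartments. With bins sorted by the label on which both libraries of the other knockdown agreed, Brg1KD bins in A.1.1 had a mean shift of -0.00711 classes (95% interval -0.0272 to 0.00966 over resampled chromosomes) and those in B.2.2 of 0.000552, and the other subcompartments ranged from -0.167 (A.2.2) to -0.0619 (A.1.2), with -0.118 in B.2.1. In Ino80KD, A.1.1 had 0.0116, B.2.2 had -0.0302 (-0.0550 to -0.00771), and the others ranged from -0.159 (B.1.1) to -0.0283 (A.1.2). A bin in B.2.2 in control cannot move further towards B, nor a bin in A.1.1 further towards A. Here the bins were sorted by the other knockdown, so these limits hold only for a part of them. The means at both ends of the scale are therefore not directly comparable with the others. Of these B.2.2 bins, 2.35% were shifted towards B and 1.81% towards A in Brg1KD, and 2.32% and 0.943% in Ino80KD. Chromosome 8 held 134 Brg1KD bins shifted towards B and 10 towards A, while chromosome 2 held 57 and 89.

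Genes of other lineages carried loops in all 3 lists. Lhx1, a transcription factor of the mesendoderm list, had 4 in control, 4 in Brg1KD and 3 in Ino80KD, and Foxa2, of the endoderm, had 3 in each. Of 39 Hox genes, 16, 15 and 16 had a loop at an end of the gene, and 0 of the 9 genes of the 2-cell-like list had one.

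A hypothesis was that loops of a knockdown list alone lie where the rank rose, and loops of the control list alone where it fell. Anchors of the 1259 loops in Brg1KD and not in control had a mean shift of -0.0407 classes, and those of the 1149 loops in control and not in Brg1KD -0.124, a difference of 0.0833 (rotation, that is permutation, p = 0.0001, the smallest possible). The difference was 0.0856 and 0.0810 within the batches. Both means lay below 0, and anchors of control loops with a Brg1KD partner had -0.0845. With class-adjusted shifts, chosen after seeing the data, anchors of Brg1KD loops alone had a mean of 0.0447 classes. Those of control loops alone then had -0.0326, and those of control loops with a Brg1KD partner -0.00235. Whether the rank rose at anchors of Brg1KD loops alone thus depends on this adjustment and stays open. By the unadjusted shifts the rank at these anchors fell less, and did not rise. In Ino80KD the difference was 0.0200 (permutation p = 0.220; 855 and 1282 loops), which decides nothing. Loops and subcompartments come from the same libraries, so contacts that differ by chance may move both, and the difference of 0.0833 does not separate this from a link between these kinds of structure.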
